A study of Rattus norvegicus with 11 samples.

How the data were processed

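Kidney cells of 11 male ZSF1 rats were profiled by droplet single-cell RNA sequencing, in 4 lean rats, 4 obese rats and 3 obese rats given enalapril. Per the labels' protocols, the kidneys were perfused, digested with a tissue dissociation kit, cleared of debris and dead cells, and loaded at 10000 cells per reaction. The submitters' processing notes name Cell Ranger 7.0.1, Seurat 4.3.0 and the rat genome build rn6, without saying what each was used for. The filters on cells, the treatment of doublets and of free RNA, the method of clustering and the genes used to name the cell types are not given in the sources used here.

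The analysis started from a table of 114615 cells that the authors deposited, with 1 line per cell and no gene values. UMIs per cell and genes per cell are counts deposited by the authors, not normalized, per the file headers and the whole-number values. The share of UMIs from mitochondrial genes is a percent deposited by the authors and reached 49.987, and no deposited cell had more than 2971 genes. The S and G2M values are a score per cell deposited by the authors, with the phase that was called from them, and the method is not given in the sources used here. The table also gives each cell the group and 1 of 21 cell type names from the authors. Map coordinates were not used. A cell was assigned to its animal through the sample code in the labels, and 0 cells had a code without an animal or a group that differed from the labels. No gene could be tested, and no clustering was repeated.

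The authors' names were read in their usual renal sense, which the table itself does not spell out: PCT and PST as convoluted and straight proximal tubule, DTL as descending thin limb, TAL as thick ascending limb, MD as macula densa, DCT as distal convoluted tubule, CNT as connecting tubule, PC as principal cells, IC-A and IC-B as intercalated cells of type A and type B, GEC as glomerular endothelial cells, Endo as other endothelial cells, Podo as podocytes and Uro as urothelial cells. Joint names such as PCT/PST and Mono/Macro were kept as the authors gave them. The types were gathered into 9 compartments by rules fixed before the data were examined. Podo/Stroma spans a pair of the planned compartments and was kept as podocyte or stroma, and Uro matched none of them and stands as other.

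The number of cells of each type in each animal was the unit of the tests, with the animal as the replicate. Counts were fitted with edgeR 4.0.16 (quasi-likelihood F test, robust, no trend of the dispersion on abundance) with all cells of the animal as the library size, in 1 fit over the 3 groups with 3 contrasts. Types with a mean under 10 cells per animal were left out, which removed Endo (38 cells) and left 20 types. The same test was run on 9 compartments, and on 17 types with the cells of their compartment as the library size. Benjamini-Hochberg adjustment was made within each contrast and family, with a threshold of 0.05. Shares are given as the mean over animals ± SD. Fold changes are on the log2 scale ± SE. For edgeR the SE was derived from the test, as the absolute log2 fold change over the square root of F. Values from limma on logit shares are differences of log2 odds. These are larger in size than log2 fold changes where a type makes up much of its total. Values with 1 number per animal were compared with exact two-sided permutation tests, which can reach 0.0286 with 4 against 4 animals and 0.0571 with 4 against 3 animals. Medians of UMIs, genes and mitochondrial percent per type, from at least 20 cells in an animal, were compared with limma 3.58.1. So were the percents of cells called S or G2M and the mean S and G2M scores per type. UMIs and genes were on the log2 scale, percents and scores on the original scale. The exact Clopper-Pearson intervals of single shares (95%) cover counting error only. Other software was DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

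The cell types named in the text were chosen by a rule fixed before the data were examined. It takes each type past the threshold in any contrast, the 5 largest absolute log2 fold changes of each contrast, and the proximal tubule, podocyte, endothelial, stromal, macrophage and T cell types whatever their result. Other types are named only where a count or a setting concerns them. The share of all immune cells, the mitochondrial percent of single types and the count of cells with at least 5% mitochondrial UMIs were chosen after the shares were seen.

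The tests of cell type counts were checked on simulated counts that took the cell types, totals and spread of the real animals. Each type was drawn apart from the others, so a rise of 1 type did not lower the shares of the rest. The simulations thus leave out that coupling of shares. For obese against lean rats, 1.33% of unchanged types were called over 100 simulations with 20 types, and 26.7%, 71.5% and 98.1% of types changed 2-fold, 3-fold and 5-fold were called with the right sign. For enalapril-treated against untreated obese rats these shares were 1.27%, 25.5%, 62.6% and 93.8%. For enalapril-treated obese against lean rats, 0.300% of unchanged types were called. The limma test of medians was checked on simulated values with 1 fixed spread for all types, not that of the real animals. It called 98.1% of types changed 4-fold in obese against lean rats, and 1.46% of unchanged types, over 18 types.

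The animals held between 4232 and 18427 cells, and between 1817129 and 56007489 UMIs in all. Every pair of animals within a group differed in its cell type counts beyond sampling noise, so each animal was counted as 1 replicate. The replicate numbers did not pair the animals by the rule set for this: 5 of 10 same-numbered pairs had a correlation over 0.1 (from -0.444 to 0.516), and 8 of 11 animals correlated best with their own number, a hint from the data and not the design. The sample codes share a prefix between some animals of a group. What the prefix stands for is not given in the sources used here, and no prefix spans more than 1 group, so it cannot be told apart from the group by comparing prefixes. Alternatives covered DESeq2, TMM factors, limma on logit shares with 0.5 cells added, exact permutation, the replicate number as a block, the prefix as a correlated block, fits with only the 2 groups compared, no minimum of cells or a mean of at least 50, shares outside the proximal tubule, cells with at least 1000 UMIs, cells under the median mitochondrial percent, and each animal left out in turn. Settings added after the data were seen left out the 2 shallowest libraries or kept cells with at least 5% mitochondrial UMIs.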

Results

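Single-cell RNA sequencing was carried out on kidneys of ZSF1 rats, a strain whose obese animals lack a working leptin receptor and serve as a model of diabetic kidney disease. The rats were males, 12 weeks old on arrival. There were 4 lean rats, 4 obese rats and 3 obese rats that drank enalapril in their water, and the untreated obese rats drank the vehicle. The labels give lean and untreated obese rats alike the treatment none and do not say whether the lean rats drank the vehicle. Enalapril inhibits angiotensin-converting enzyme and so blocks the renin-angiotensin-aldosterone system. The series title names blockade of this system, and the comparisons concern the cell makeup of the kidney, since the deposited table gives the authors' cell type, UMIs, genes and mitochondrial share of each cell but no gene values.

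The table held 114615 cells. Lean rats 1 to 4 had 11148, 4232, 7701 and 6469 cells, obese rats 1 to 4 had 10844, 7052, 11540 and 18427, and enalapril-treated obese rats 1 to 3 had 17948, 11452 and 7802. In 6 of the 11 animals this was more than the 10000 cells that the labels give as loaded. The median UMIs per cell were 1417.5, 407, 2231 and 2065 in the lean rats, 1939.5, 2054, 3092 and 2521 in the obese rats, and 1132, 2737 and 2492 in the treated rats. Lean rat 2 was by far the shallowest, with a total of 1817129 UMIs, at most 1703 UMIs in a cell and 12 cells of at least 1000 UMIs. The deepest animal, obese rat 4, had 56007489 UMIs. Counting error was small for common types and large for rare ones. T cells made up 3.71% of the cells of lean rat 2 (exact 95% Clopper-Pearson interval 3.16% to 4.32%) and 14.5% of those of obese rat 4 (14.0% to 15.1%), whereas the B cell share of lean rat 2, 0.165%, had an interval of 0.0665% to 0.341%. Such intervals cover counting error only.

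The first comparison asked how the cell makeup of the obese kidney differed from that of the lean kidney. Immune cells made up 34.4% ± 2.74 of the cells in obese rats (SD, n = 4) and 13.4% ± 5.96 in lean rats (SD, n = 4), and each of the 4 obese animals lay above all lean animals. Myeloid cells rose from 6.40% ± 2.72 to 17.7% ± 3.27 (log2 fold change 1.46 ± 0.37, adjusted p = 0.00548, 4 of 4 obese animals above every lean animal). Lymphoid cells rose from 7.04% ± 3.31 to 16.8% ± 0.835 (1.25 ± 0.37, adjusted p = 0.0126, 4 of 4). The distal and connecting tubule, the segment of fine control of sodium, calcium and potassium, fell from 9.27% ± 2.92 to 2.91% ± 1.12 (-1.67 ± 0.39, adjusted p = 0.00548, 4 of 4 obese animals below every lean animal). The collecting duct fell from 13.5% ± 8.58 to 5.26% ± 2.54 (-1.36 ± 0.46, adjusted p = 0.0186, 3 of 4 below every lean animal). The proximal tubule, the largest compartment, held 46.2% ± 10.3 of lean and 43.8% ± 10.6 of obese cells (-0.08 ± 0.32, adjusted p = 0.808).

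In all, 5 of 9 compartments differed in edgeR's test, the fifth being the urothelial cells. The loop of Henle (-0.22 ± 0.40, adjusted p = 0.662), the endothelium (-0.61 ± 0.52, adjusted p = 0.339) and podocyte or stroma cells (0.64 ± 0.49, adjusted p = 0.315) did not pass. The sum of both immune compartments differed by 21.0 percentage points between obese and lean rats, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 animals allow, and 0.0857 after adjustment over 3 comparisons. In an exact permutation test of logit shares, the myeloid, lymphoid and distal compartments reached that smallest p, with an adjusted p of 0.0857, and 0 of 9 were called. Without lean rat 2 the collecting duct was no longer called (-0.81 ± 0.39, adjusted p = 0.0594) and the endothelium was (-0.95 ± 0.39, adjusted p = 0.0376). The collecting duct also missed the threshold without obese rat 1 (-1.26 ± 0.53, adjusted p = 0.0602) or obese rat 4 (-1.12 ± 0.46, adjusted p = 0.0567). So it did among cells with at least 1000 UMIs (-0.91 ± 0.45, adjusted p = 0.0858) and under the median mitochondrial percent (-1.60 ± 0.70, adjusted p = 0.0652). The urothelial cells missed it without obese rat 4 (-1.98 ± 0.82, adjusted p = 0.0567) and shrank to -1.11 ± 0.49 (adjusted p = 0.0459) without lean rat 2. The lymphoid cells missed the threshold among cells with at least 1000 UMIs (0.99 ± 0.46, adjusted p = 0.0755).

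**Figure D1:**
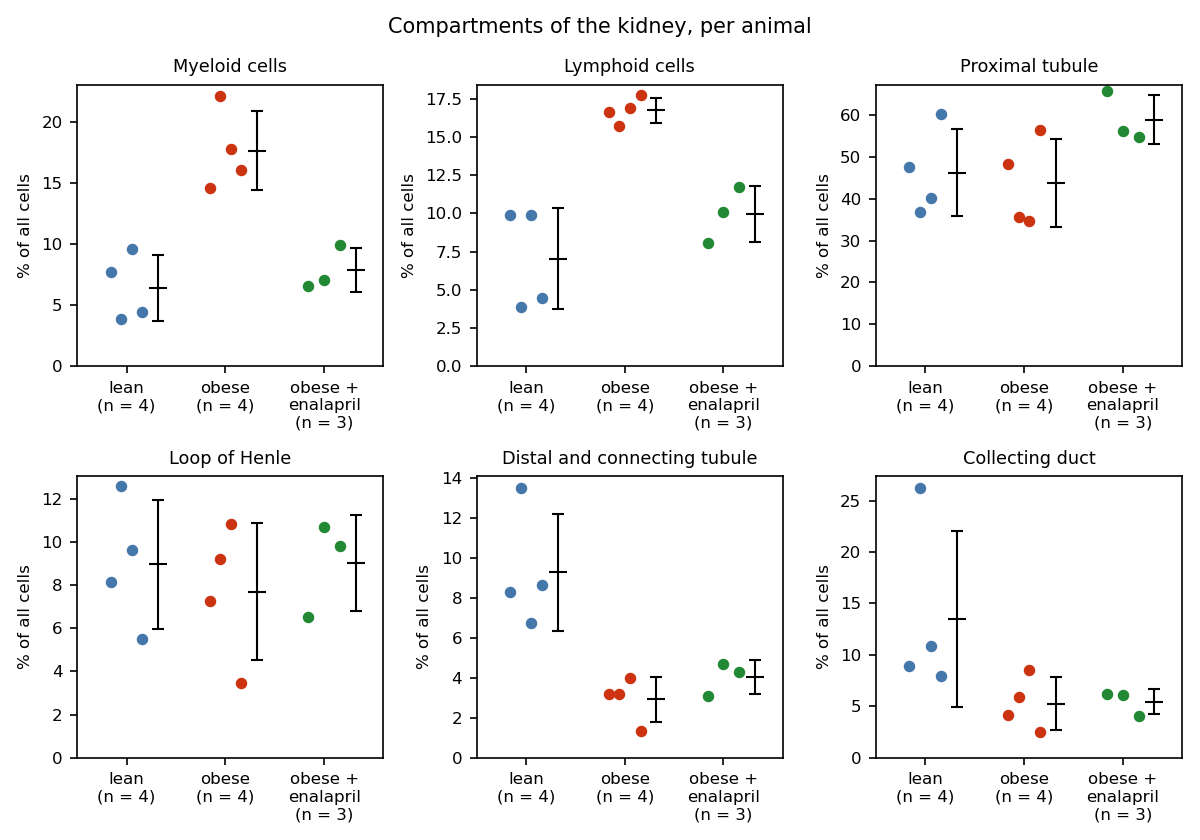
Share of 6 compartments among all cells, in percent, with 1 point per animal and the mean ± SD beside the points (lean n = 4, obese n = 4, enalapril-treated obese n = 3). The obese animals lie above all others for myeloid and lymphoid cells and below all lean animals for the distal and connecting tubule, and the lean animal at 26.2% of collecting duct cells is lean rat 2.

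Of 20 cell types tested, 6 rose and 6 fell in obese rats. The exact permutation test of logit shares called 0 of 20, as the 8 types without overlap between the groups, monocytes, Mono/Macro, T and B cells, PST, DCT, IC-B and TAL, had an adjusted p of 0.0714. Among the immune cells, B cells, which make antibodies, rose from 0.167% ± 0.0398 to 1.74% ± 1.05 (log2 fold change 3.39 ± 0.54, adjusted p = 0.000131). Cells named monocyte or macrophage (Mono/Macro) rose from 0.371% ± 0.127 to 1.62% ± 0.230 (2.12 ± 0.43, adjusted p = 0.000750). Monocytes rose from 3.58% ± 1.79 to 11.3% ± 3.00 (1.66 ± 0.42, adjusted p = 0.00461) and T cells from 6.87% ± 3.30 to 15.0% ± 0.899 (1.13 ± 0.39, adjusted p = 0.0195). For each of these 4 types, 4 of 4 obese animals lay above every lean animal. Macrophages were at 2.45% ± 0.937 and 4.74% ± 1.07 and did not pass (0.94 ± 0.44, adjusted p = 0.0705). They passed without lean rat 3 (1.18 ± 0.49, adjusted p = 0.0398) or treated rat 1 (0.94 ± 0.38, adjusted p = 0.0439) and in DESeq2 (0.97 ± 0.40, adjusted p = 0.0245). Without lean rat 2 or lean rat 4 the T cell change missed the threshold (0.92 ± 0.44, adjusted p = 0.0715, and 0.96 ± 0.40, adjusted p = 0.0509). It also missed it among cells with at least 1000 UMIs (0.85 ± 0.51, adjusted p = 0.191) and among cells under the median mitochondrial percent (1.23 ± 0.53, adjusted p = 0.0624).

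Along the nephron, the types that rose were straight proximal tubule (PST), from 3.64% ± 1.49 to 8.87% ± 2.49 (1.28 ± 0.39, adjusted p = 0.0118, 4 of 4 obese animals above every lean animal), and descending thin limb (DTL). DTL rose from 0.883% ± 0.350 to 2.74% ± 1.44 (1.62 ± 0.49, adjusted p = 0.0118, 3 of 4). Convoluted proximal tubule (PCT), where most filtered glucose and amino acids are taken up, was at 30.3% ± 5.56 and 24.2% ± 6.21 (-0.32 ± 0.35, adjusted p = 0.406), and the joint PCT/PST type at 12.3% ± 3.88 and 10.7% ± 3.76 (-0.20 ± 0.38, adjusted p = 0.601). Glomerular endothelial cells were at 7.67% ± 4.48 and 5.02% ± 2.22 (-0.62 ± 0.51, adjusted p = 0.290). Podo/Stroma cells were at 0.499% ± 0.287 and 0.792% ± 0.359 (0.64 ± 0.49, adjusted p = 0.269). The PST change missed the threshold among cells with at least 1000 UMIs (1.08 ± 0.51, adjusted p = 0.0923) and among those with at least 5% mitochondrial UMIs (1.23 ± 0.60, adjusted p = 0.0808). Among cells under the median mitochondrial percent neither PST (0.18 ± 0.56, adjusted p = 0.795) nor DTL (1.10 ± 0.58, adjusted p = 0.111) was called. The same setting called PCT lower in obese rats (-1.26 ± 0.49, adjusted p = 0.0377). It also called TAL (-2.18 ± 0.53, adjusted p = 0.00279) and TAL/MD (-2.04 ± 0.67, adjusted p = 0.0188) lower. However, only 30.2% ± 5.88 of obese against 56.3% ± 16.7 of lean non-immune cells had under 10% mitochondrial UMIs. The setting itself can thus lower the shares of tubule types in obese rats. Calls that it made or ended were therefore not read as gains or losses of cells.

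In the main fit, the types that fell belonged to the distal nephron and the urothelium. Distal convoluted tubule (DCT) cells, which take up sodium through the thiazide-sensitive cotransporter, fell from 5.35% ± 1.27 to 1.28% ± 0.552 (-2.07 ± 0.43, adjusted p = 0.000750, 4 of 4 obese animals below every lean animal). Intercalated cells, which handle acid and base, fell as type B (4.09% ± 2.17 to 1.23% ± 0.664, -1.73 ± 0.51, adjusted p = 0.0118, 4 of 4). They also fell as type A (4.85% ± 3.92 to 1.56% ± 0.806, -1.64 ± 0.53, adjusted p = 0.0141, 3 of 4) and as the joint IC-A/B type (3.33% ± 2.38 to 1.47% ± 0.800, -1.18 ± 0.49, adjusted p = 0.0468, 3 of 4). The joint DCT/CNT type fell from 3.92% ± 2.47 to 1.64% ± 0.628 (-1.26 ± 0.45, adjusted p = 0.0213, 3 of 4). Urothelial cells fell from 0.477% ± 0.585 to 0.0993% ± 0.0406 (-2.24 ± 0.71, adjusted p = 0.0134, 1 of 4). Principal cells, which take up water and sodium in the same duct, were at 1.19% ± 0.294 and 1.00% ± 0.464 (-0.26 ± 0.42, adjusted p = 0.583). Without lean rat 2 the calls of IC-A (-0.92 ± 0.44, adjusted p = 0.0715), IC-A/B (-0.54 ± 0.44, adjusted p = 0.309), DCT/CNT (-0.73 ± 0.44, adjusted p = 0.151) and urothelial cells (-1.09 ± 0.52, adjusted p = 0.0715) were lost. In that fit 7 types were called in place of 12. DCT/CNT also missed the threshold without obese rat 2 (-1.22 ± 0.52, adjusted p = 0.0584) or obese rat 4 (-1.03 ± 0.44, adjusted p = 0.0545). Urothelial cells missed it without obese rat 4 (-1.98 ± 0.80, adjusted p = 0.0529), and IC-A/B kept its call in 4 of 11 fits with 1 animal left out. limma called neither urothelial cells (-1.45 ± 0.66, adjusted p = 0.0630) nor IC-A/B cells (-1.17 ± 0.50, adjusted p = 0.0562). With the replicate number as a block IC-A/B was lost (-1.09 ± 0.48, adjusted p = 0.0804) and TAL/MD was called (-0.81 ± 0.25, adjusted p = 0.0199), as it was without obese rat 3 (-1.14 ± 0.49, adjusted p = 0.0478). Among cells with at least 1000 UMIs, the calls of IC-A (-0.98 ± 0.50, adjusted p = 0.115), IC-A/B (-0.54 ± 0.51, adjusted p = 0.382), DCT/CNT (-0.67 ± 0.50, adjusted p = 0.280) and urothelial cells (-1.35 ± 0.59, adjusted p = 0.0643) were lost. Among cells under the median mitochondrial percent, type B intercalated cells had a larger but uncertain change (-2.51 ± 1.65, adjusted p = 0.217), as did type A (-2.52 ± 1.15, adjusted p = 0.0943).

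DCT cells differed between lean and obese rats in their mitochondrial share. Their median was 1.51% ± 2.22 in lean rats (SD, n = 4), 30.1% ± 4.14 in obese rats (SD, n = 4) and 19.8% ± 11.7 in treated rats (SD, n = 3). DCT was the only type of 18 whose median mitochondrial percent differed between obese and lean rats in limma's test (28.6 percentage points). It was also the only type called between treated obese and lean rats. Without lean rat 2 the call against obese rats was kept and that against treated rats was lost. Of the lean DCT cells, 73.7% ± 20.5 had under 5% mitochondrial UMIs, against 13.7% ± 8.13 in obese rats. The lean value of DCT was the highest of all types. Some lean types had similar shares, such as PCT/PST (72.8% ± 16.5), monocytes (67.4% ± 12.8) and T cells (65.9% ± 17.7). In obese rats these were at 49.6% ± 14.6, 48.0% ± 11.1 and 41.1% ± 12.6. Among the other distal tubule and collecting duct types of lean rats, only IC-A/B cells (63.3% ± 10.0) came near DCT. DCT/CNT (13.1% ± 7.34), PC (21.8% ± 31.5), IC-A (16.9% ± 23.5) and IC-B cells (4.51% ± 6.74) lay far lower. The gap of DCT to obese rats was the widest of all types. Counting only cells with at least 5% mitochondrial UMIs, a setting chosen after this was seen, DCT made up 2.00% ± 1.13 of lean and 1.46% ± 0.572 of obese cells, and the DCT change was not called (-0.48 ± 0.60, adjusted p = 0.543). That follows in large part from the lean DCT cells so left out. DCT/CNT cells had medians of 21.6% ± 7.78 and 21.9% ± 2.55.

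Within their own compartments, 4 of 17 types differed between obese and lean rats. PST rose from 7.74% ± 1.66 to 20.7% ± 5.14 of the proximal tubule (1.42 ± 0.22, adjusted p = 0.00100, 4 of 4 obese animals above every lean animal). DTL rose from 10.6% ± 4.25 to 33.3% ± 11.3 of the loop of Henle (1.64 ± 0.35, adjusted p = 0.00694, 4 of 4). TAL/MD, the thick limb with the salt-sensing macula densa, fell from 62.5% ± 11.8 to 42.6% ± 5.07 of the loop (-0.55 ± 0.15, adjusted p = 0.0169, 3 of 4 below every lean animal). B cells rose from 2.80% ± 1.32 to 10.3% ± 5.78 of the lymphoid cells (2.15 ± 0.56, adjusted p = 0.0169, 4 of 4). The TAL/MD call was lost without lean rat 3 (-0.53 ± 0.17, adjusted p = 0.0541) or obese rat 1 (-0.50 ± 0.16, adjusted p = 0.0578). The B cell call was lost without lean rat 1 (1.78 ± 0.61, adjusted p = 0.0534) or lean rat 3 (2.11 ± 0.67, adjusted p = 0.0541). Among cells under the median mitochondrial percent PST (0.89 ± 0.45, adjusted p = 0.141) and TAL/MD (-0.91 ± 0.37, adjusted p = 0.0953) were not called. Some settings added calls. Without lean rat 2 these were DCT (-0.59 ± 0.16, adjusted p = 0.0161), DCT/CNT (0.69 ± 0.20, adjusted p = 0.0195) and Mono/Macro cells (0.92 ± 0.25, adjusted p = 0.0161). limma added DCT (-0.99 ± 0.39), DCT/CNT (0.99 ± 0.39) and PC (1.06 ± 0.41), each at an adjusted p of 0.0473. It also added T cells (-1.90 ± 0.50, adjusted p = 0.00781). These limma values are differences of log2 odds. T cells went from 97.2% ± 1.32 to 89.7% ± 5.78 of the lymphoid cells, and edgeR did not call them (-0.12 ± 0.10, adjusted p = 0.348). As the rest of a pair, T cells mirror B cells within their compartment and DCT mirrors DCT/CNT, so such calls are not separate results.

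**Figure D2:**
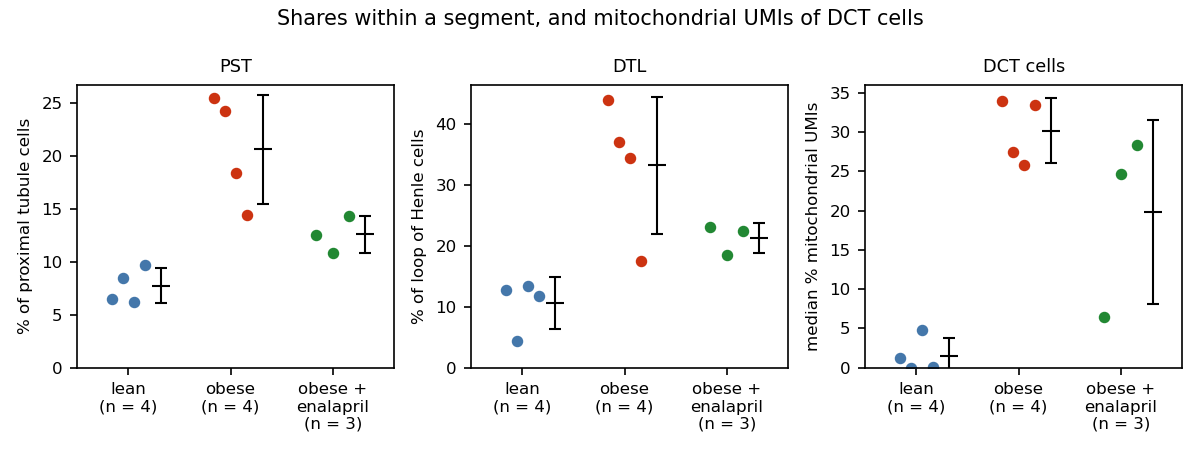
PST in percent of proximal tubule cells (left), DTL in percent of loop of Henle cells (middle) and median mitochondrial percent of DCT cells (right), with 1 point per animal and the mean ± SD beside the points (lean n = 4, obese n = 4, enalapril-treated obese n = 3). PST averaged 7.74%, 20.7% and 12.6% in the 3 groups, and the lean DCT medians averaged 1.51%.

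The second comparison asked how enalapril changed the obese kidney. Immune cells made up 17.8% ± 3.55 of the cells in treated rats (SD, n = 3) and 34.4% ± 2.74 in untreated obese rats (SD, n = 4), and each treated animal lay below all untreated ones. Monocytes were at 4.04% ± 1.01 against 11.3% ± 3.00, T cells at 9.06% ± 1.33 against 15.0% ± 0.899, and Mono/Macro cells at 0.762% ± 0.406 against 1.62% ± 0.230, each with 3 of 3 treated animals below all untreated ones. PCT made up 39.2% ± 3.52 of the cells of treated rats and 24.2% ± 6.21 of those of untreated rats, with 3 of 3 above all untreated animals. None of these differences passed edgeR's adjusted test in the main fit. The immune share differed by -16.6 percentage points, with an exact two-sided permutation p of 0.0571, the smallest that 3 against 4 animals allow, and 0.0857 after adjustment over 3 comparisons.

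edgeR called 0 of 20 cell types between treated and untreated obese rats, with 2 at an unadjusted p under 0.05, and 0 of 9 compartments, with 1 at an unadjusted p under 0.05. limma on logit shares and the permutation test called 0 in both families. DESeq2 called 1 in each, monocytes (-1.49 ± 0.45, adjusted p = 0.0169) and myeloid cells (-1.37 ± 0.42, adjusted p = 0.0110). In edgeR the values were -1.48 ± 0.46 (adjusted p = 0.0932) for monocytes and -1.17 ± 0.40 (adjusted p = 0.0953) for myeloid cells, which were at 7.85% ± 1.81 against 17.7% ± 3.27. The next largest changes were Mono/Macro cells (-1.10 ± 0.45, adjusted p = 0.240), IC-A/B cells (-1.06 ± 0.54, adjusted p = 0.337), B cells (-0.95 ± 0.52, adjusted p = 0.337) and Podo/Stroma cells (-0.85 ± 0.53, adjusted p = 0.371). Each was lower than the untreated mean in 3 of 3 treated animals. T cells (-0.73 ± 0.42, adjusted p = 0.340), PCT (0.70 ± 0.37, adjusted p = 0.337), and macrophages (-0.64 ± 0.48, adjusted p = 0.440) did not pass. Nor did PST (-0.26 ± 0.41, adjusted p = 0.670), glomerular endothelial cells (-0.26 ± 0.56, adjusted p = 0.680) or PCT/PST (0.20 ± 0.41, adjusted p = 0.680). edgeR called monocytes when only these 2 groups were fitted (-1.48 ± 0.43, adjusted p = 0.0473), without lean rat 2 (-1.48 ± 0.45, adjusted p = 0.0261) and among cells with at least 1000 UMIs (-1.88 ± 0.53, adjusted p = 0.0104), and not without any other single animal. Without the 2 shallowest libraries they were called as well (-1.67 ± 0.53, adjusted p = 0.0482). With the replicate number as a block, which the animals were not shown to share, edgeR called monocytes (-1.67 ± 0.46), Mono/Macro cells (-1.36 ± 0.34) and PCT (0.85 ± 0.24), each at an adjusted p of 0.0463. The same fit called myeloid cells (-1.31 ± 0.33) and the proximal tubule (0.59 ± 0.14), both at an adjusted p of 0.0278. Myeloid cells were also called with only these 2 groups (-1.17 ± 0.30, adjusted p = 0.0200), without lean rat 2 (-1.17 ± 0.40, adjusted p = 0.0425) and among cells with at least 1000 UMIs (-1.39 ± 0.46, adjusted p = 0.0353). limma with the code prefix of the samples as a correlated block called monocytes (-1.60 ± 0.38, adjusted p = 0.0143), Mono/Macro cells (-1.30 ± 0.38, adjusted p = 0.0354) and PCT (1.07 ± 0.34, adjusted p = 0.0441), and among compartments myeloid cells (-1.39 ± 0.35, adjusted p = 0.0113). The correlation within a prefix was estimated as -0.283 for types and -0.352 for compartments, and a negative value narrows the errors of differences between prefixes, so these calls add little.

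Within compartments, 1 of 17 types differed. IC-A/B cells fell from 29.1% ± 12.1 of the collecting duct in untreated obese rats to 12.8% ± 0.205 in treated rats (-1.19 ± 0.30, adjusted p = 0.0481, 3 of 3 treated animals below all untreated ones). This call was kept in 2 of 11 fits with 1 animal left out, over which the change ran from -1.40 to -0.92 and the adjusted p reached 0.177. It was lost in limma (-1.40 ± 0.42, adjusted p = 0.0819), in a fit of only these 2 groups (-1.19 ± 0.34, adjusted p = 0.0870) and with the replicate number as a block (-0.95 ± 0.26, adjusted p = 0.115). PST made up 12.6% ± 1.74 of the proximal tubule against 20.7% ± 5.14 (-0.71 ± 0.23), and TAL/MD 59.8% ± 1.14 of the loop against 42.6% ± 5.07 (0.49 ± 0.16), each with an adjusted p of 0.0680 and no overlap between the groups. DESeq2 called both (-0.71 ± 0.25 and 0.48 ± 0.17, adjusted p = 0.0262), and edgeR called PST without obese rat 4 (-0.85 ± 0.21, adjusted p = 0.0448).

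**Figure D3:**
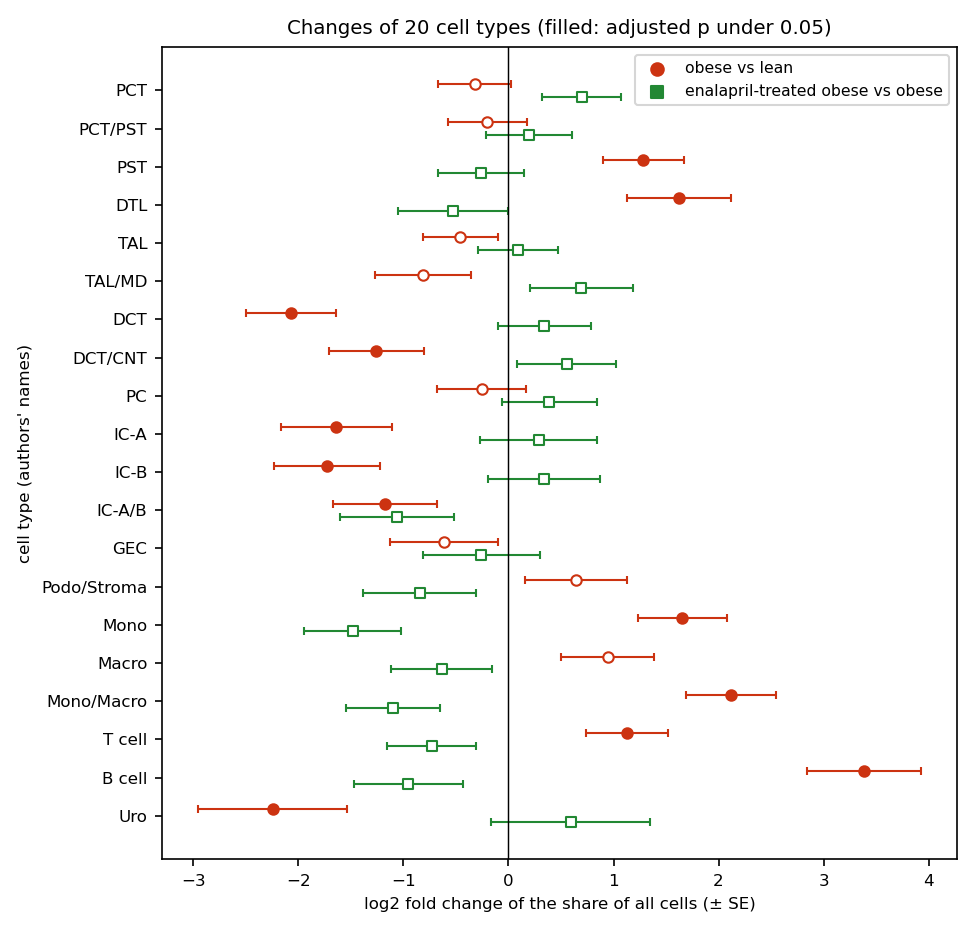
log2 fold change ± SE of the share of all cells for 20 cell types under the authors' names, for obese against lean rats (circles, n = 4 and 4) and enalapril-treated against untreated obese rats (squares, n = 3 and 4), with filled symbols for adjusted p under 0.05. There are 12 filled circles and 0 filled squares, and 18 of the 20 types have opposite signs in the 2 comparisons.

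The third comparison set the treated obese rats against the lean rats. B cells rose from 0.167% ± 0.0398 in lean rats to 0.908% ± 0.606 in treated rats (2.43 ± 0.55, adjusted p = 0.00679). IC-A/B cells fell from 3.33% ± 2.38 to 0.698% ± 0.161 (-2.24 ± 0.57, adjusted p = 0.00938). DCT cells fell from 5.35% ± 1.27 to 1.61% ± 0.373 (-1.73 ± 0.47, adjusted p = 0.0100). All 3 changes were seen in 3 of 3 treated animals against every lean animal. These were the 3 of 20 types called. Monocytes were at 4.04% ± 1.01 and 3.58% ± 1.79 (0.17 ± 0.44, adjusted p = 0.830) and T cells at 9.06% ± 1.33 and 6.87% ± 3.30 (0.40 ± 0.42, adjusted p = 0.503). The immune share differed by 4.37 percentage points (exact two-sided permutation p = 0.400, 0.400 after adjustment, 1 of 3 treated animals above every lean animal). The proximal tubule held 58.9% ± 5.92 of treated and 46.2% ± 10.3 of lean cells. Outside it, immune cells made up 43.2% ± 4.31 of treated and 25.2% ± 9.97 of lean cells, without overlap. The exact two-sided permutation p of that difference was 0.0571, the smallest possible here and not adjusted. Without treated rat 1 the DCT call was lost (-1.55 ± 0.54, adjusted p = 0.0515). Without lean rat 2 the IC-A/B change shrank to -1.61 ± 0.48 (adjusted p = 0.00776). Without treated rat 3, which had 1.60% of B cells against 0.485% and 0.637% in the other treated rats, the B cell change shrank to 1.75 ± 0.56 (adjusted p = 0.0440). Among cells with at least 5% mitochondrial UMIs DCT made up 1.86% ± 0.489 of treated and 2.00% ± 1.13 of lean cells.

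Further types did not pass in this comparison. Urothelial cells (-1.65 ± 0.75, adjusted p = 0.101) and IC-B cells (-1.39 ± 0.55, adjusted p = 0.0846) had the next largest changes. DESeq2 called both (-1.84 ± 0.73 and -1.40 ± 0.55, adjusted p = 0.0402). Urothelial cells passed without lean rat 3 (-2.02 ± 0.68, adjusted p = 0.0364), and DTL without obese rat 4 (1.09 ± 0.36, adjusted p = 0.0435). PST was at 1.02 ± 0.41 (adjusted p = 0.0846), passing without lean rat 4 (1.35 ± 0.40, adjusted p = 0.0205) and with the replicate block (1.21 ± 0.34, adjusted p = 0.0382), which also called IC-A (-1.46 ± 0.45, adjusted p = 0.0444). Mono/Macro cells were at 1.02 ± 0.45 (adjusted p = 0.0974). With the proximal tubule left out they were called (1.39 ± 0.41, adjusted p = 0.0144), as was DTL (1.46 ± 0.47, adjusted p = 0.0162). Glomerular endothelial cells (-0.88 ± 0.57, adjusted p = 0.278), PCT (0.37 ± 0.37, adjusted p = 0.503), and macrophages (0.31 ± 0.47, adjusted p = 0.697) were not called. Glomerular endothelial cells passed among cells with at least 1000 UMIs (-1.44 ± 0.54, adjusted p = 0.0445). Podo/Stroma cells (-0.20 ± 0.53, adjusted p = 0.830) and PCT/PST (-0.0049 ± 0.41, adjusted p = 0.991) were not called either. edgeR called 0 of 9 compartments, with 2 at an unadjusted p under 0.05, limma and the permutation test called 0, and DESeq2 called 2, the distal and connecting tubule and the collecting duct. edgeR called the distal and connecting tubule without lean rat 3 (-1.33 ± 0.45, adjusted p = 0.0425) or obese rat 4 (-1.21 ± 0.34, adjusted p = 0.0317). With the replicate block it called that tubule (-1.39 ± 0.36), the collecting duct (-1.41 ± 0.43) and the proximal tubule (0.51 ± 0.14), each at an adjusted p of 0.0407. Within compartments 5 of 17 types were called, all at an adjusted p of 0.0478. PC rose (1.23 ± 0.36), as did B cells (1.88 ± 0.59) and PST (0.71 ± 0.23), while IC-A/B cells (-0.92 ± 0.30) and DCT cells (-0.57 ± 0.19) fell, each in 3 of 3 treated animals against every lean animal. Each of these calls was lost in most of the 11 fits with 1 animal left out (PC kept in 5, the others in 2), with the adjusted p reaching 0.143, and all 5 were lost with the replicate block. DCT took the opposite sign among cells with at least 5% mitochondrial UMIs (0.32).

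Across the 20 types, the log2 changes after enalapril ran against those of obesity, with a Pearson correlation of -0.722, a Spearman correlation of -0.68 and a covariance of -0.76. The 4 untreated obese rats enter both comparisons with opposite signs, so chance alone gives negative values, and cell types are not independent replicates. In 200 simulations with no effect in either comparison the Pearson correlation averaged -0.445 and its lowest 5% lay at or below -0.723, so the observed correlation was not below that bound. The covariance averaged -0.11 in the simulations, with its lowest 5% at or below -0.23, and 0% were as low as the observed one. Simulations without an effect of obesity have small changes and hence small covariances, so this bound does not test enalapril alone. With the obese rats split so that each comparison used 2 of them, the covariance lay between -0.93 and -0.41 and the correlation between -0.827 and -0.316 over 6 splits. Of the 20 types, 18 had opposite signs in both comparisons, against a mean of 13.1 in the simulations.

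Depth and mitochondrial share were compared in the same groups. The median UMIs per cell averaged 1530 ± 827 in lean, 2402 ± 524 in obese and 2120 ± 865 in treated rats (SD, n = 4, 4 and 3), and the median mitochondrial percent 7.48% ± 3.52, 12.9% ± 2.77 and 11.9% ± 7.35. The exact two-sided permutation p for the mitochondrial difference between obese and lean rats was 0.0286, and 0.343 after adjustment over the 12 tests of cells, UMIs, genes and mitochondrial percent, of which 0 passed and 1 had an unadjusted p under 0.05. Within types, limma called 0 of 18 for the median UMIs and 0 of 18 for the median genes in each comparison, with 2, 0 and 1 types at an unadjusted p under 0.05 for both measures. The only call that appeared with 1 animal left out was for the UMIs of DTL cells in obese against lean rats, without lean rat 2.

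The cell cycle phases that the authors called were also compared. Cells called G2M made up 21.2% ± 2.27 of lean, 30.4% ± 2.43 of obese and 23.2% ± 2.01 of treated cells (SD, n = 4, 4 and 3). The exact two-sided permutation p was 0.0286 for obese against lean rats and 0.0571 for treated against untreated obese rats, the smallest possible for these numbers of animals, and 0.171 for both after adjustment over 6 tests. Cells called S made up 26.0% ± 10.1, 31.5% ± 1.42 and 28.3% ± 5.43. Within types, limma called the G2M share of TAL, DCT and monocytes (3 of 18) between obese and lean rats, and 0 of 18 without lean rat 2. The mean G2M score was called in 0 of 18 types, with 4 at an unadjusted p under 0.05, and in 8 of 18 without lean rat 2. These are calls from a score per cell, which depth may enter, as may free RNA, which was not measured here. They are therefore not read as a measure of cycling cells.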

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

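The tests of depth and of fewer proximal tubule cells for the immune share, and those without lean rat 2 for the distal nephron, were chosen after the results were seen. So were the G2M comparisons with lean and with treated rats apart, the share of DCT cells near the highest mitochondrial percent, the immune share itself and the DCT share among cells with at least 5% mitochondrial UMIs.

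Single animals that lay far from the rest of their group were looked for in 112 groups of 4 animals. There were 5 such values, 4 of them in lean rat 2, and chance flags about 1 in 20 groups. In lean rat 2, IC-A/B cells made up 6.90% of all cells (1.96% to 2.27% in the other lean rats), the collecting duct 26.2% (7.90% to 10.8%), Mono/Macro cells 10.4% of the myeloid cells (4.53% to 5.27%), and cells called S 10.9% (30.1% to 31.5%). This is the library with a median of 407 UMIs per cell. In obese rat 4, DTL cells made up 0.608% of all cells, against 3.21% to 3.74% in the other obese rats.

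The immune share was higher in obese than in lean and enalapril-treated rats. Among cells with at least 1000 UMIs, which leaves 3 lean rats, the lowest obese animal lay 11.4 percentage points above the highest other animal. The cells under that minimum thus do not account for the whole difference. The minimum does not make depth equal between animals, so this test cannot settle what depth contributes. A loss of proximal tubule cells from obese kidneys would have left the immune share of the other cells unchanged. Outside the proximal tubule, immune cells made up 62.5% ± 10.6 of obese and 25.2% ± 9.97 of lean cells. This argues against such a loss as the whole cause. The log2 ratio of myeloid to distal cells was 3.28 higher in obese than in lean rats. It restates the changes of those compartments and adds no test. Among cells outside the proximal tubule, the lowest obese animal also lay 5.36 points above the highest treated one. A gain of proximal tubule cells after enalapril would not have left that gap. Loss of tubule cells at an upper limit on the mitochondrial percent cannot be told apart from a real change: among cells under 10% mitochondrial UMIs the obese animals lay 6.58 points above all others, but only 30.2% ± 5.88 of obese against 56.3% ± 16.7 of lean non-immune cells were under 10%, so that this count itself raises the obese immune share. Obesity and enalapril, which the design names, stay open and untested beside it, as do the vehicle, which the lean rats are not said to have drunk, and how well immune cells came out of fibrous or inflamed tissue. Whatever the code prefix of the samples stands for is nested in the groups and cannot be told apart from them either.

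The distal and connecting tubule, and with less certainty the collecting duct, made up a lower share of the recovered cells in obese rats. Lean rat 2 alone is argued against for the distal and connecting tubule (-1.44 ± 0.39 without it, adjusted p = 0.00412) and so is the room taken by immune cells, since as a share of non-immune cells the lowest lean animal stayed 2.25 points above the highest obese one; for the collecting duct neither is settled (-0.81 ± 0.39 without lean rat 2, adjusted p = 0.0594, and an overlap of -4.31 points among non-immune cells). Of the DCT cells, 73.7% ± 20.5 in lean and 13.7% ± 8.13 in obese rats had under 5% mitochondrial UMIs, and with these left out the groups overlapped (-1.39 points between the lowest lean and the highest obese animal) with 13.3% of the difference left, which restates those percents and decides nothing on the cause. Loss of obese DCT cells at an upper limit on the mitochondrial percent may account for a part, as 26.9% ± 6.31 of obese against 3.53% ± 5.17 of lean DCT cells lay within 10 points of the highest value, without overlap, whereas for the whole distal compartment (20.4% of obese cells, 1 obese animal below the highest lean one) it cannot be told apart from a real loss. Lean DCT cells with little mitochondrial RNA, which other lean types hold too, could be nuclei, damaged cells or cells named DCT by mistake, and a true loss of DCT cells in obesity stays open, none of which these columns test. The code prefix, nested in the groups, cannot be told apart from obesity here either.

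Cells called G2M were more frequent in obese rats than in the others. With equal weights of 16 cell types the lowest obese animal stayed 1.27 points above the highest lean one (26.9% ± 1.58 and 23.1% ± 1.17, 42.1% of the difference left, exact two-sided permutation p = 0.0286, not adjusted), which argues against the mix of cell types as the whole cause of the difference from lean rats. Against treated rats the gap was -0.778 points with 33.2% left, and 38.8% of the excess over the mean of all other animals was left. Within types in obese against lean rats, the G2M score was called in 8 of 18 types without lean rat 2 and in 0 with it, and the share of G2M calls in 0 without it and in 3 with it. Among cells with 1000 to under 2000 UMIs the gap to the highest other animal was -5.20 points and 46.7% was left, so that the mix of cell types and the depth of the libraries may each account for a part, and no change in cycling was tested. Nor can the code prefix be told apart from the group for these calls.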

How the results depend on the processing

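Leaving out the 2 shallowest libraries, keeping cells with at least 5% mitochondrial UMIs, the immune share and the phases without lean rat 2 were chosen after the data were seen; the other settings were fixed before the data were examined. Over the 30 called results of named types and compartments, 733 alternative values were computed, of which 557 kept direction and call, 175 kept the direction and lost the call, and 1 turned: DCT within its compartment, treated obese against lean rats, at 0.32 among cells with at least 5% mitochondrial UMIs. Monocytes, Mono/Macro cells and B cells in obese against lean rats, and the myeloid and distal compartments, kept their call in all 13 alternatives and all 11 fits with 1 animal left out. The exact permutation test is not among these 13 alternatives and ended all calls. For monocytes, Mono/Macro cells and B cells in obese against lean rats it gave an adjusted p of 0.0714, and for the myeloid and distal compartments 0.0857. With 4 against 4 animals more types at the smallest p of 0.0286 would have let it pass, whereas with 3 treated animals the smallest p is 0.0571 and it cannot. Cells with at least 1000 UMIs leave lean rat 2 out as well. The 13 alternatives reuse the same animals and are not independent of each other. Counting cells under the median mitochondrial percent can itself raise the obese immune share and lower the obese DCT share, so it does not test these calls. Unless stated, the cause of a change was not tested.

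Counts are given for obese against lean, treated against untreated obese, and treated obese against lean rats, with 12, 0 and 3 types, 5, 0 and 0 compartments, and 4, 1 and 5 types within compartments as reported. DESeq2 called 14, 1 and 7 types, 5, 1 and 2 compartments, and 8, 4 and 6 types within compartments. limma called 10, 0 and 3, then 4, 0 and 0, then 8, 0 and 7. The permutation test called 0 in each. Fits of only the 2 groups gave 11, 1 and 3, then 5, 1 and 0, then 5, 0 and 2. The prefix as a correlated block gave 12, 3 and 5, then 4, 1 and 1, then 9, 1 and 8, with correlations estimated as -0.283, -0.352 and -0.306, which narrow the errors of differences between groups. Without the 2 shallowest libraries the counts were 7, 1 and 4, then 4, 0 and 0, then 9, 0 and 6. Cells with at least 1000 UMIs gave 6, 1 and 4, then 2, 1 and 0, then 7, 0 and 7. Cells under the median mitochondrial percent gave 9, 0 and 4, then 4, 0 and 1, then 5, 0 and 2. Cells with at least 5% mitochondrial UMIs gave 8, 0 and 2, then 4, 0 and 0, then 4, 0 and 0. Without the proximal tubule the counts were 12, 0 and 5, then 5, 0 and 0, then 3, 1 and 3. No minimum of cells gave 12, 0 and 3, then 5, 0 and 0, then 5, 0 and 0. TMM factors gave 12, 0 and 3 types and 5, 0 and 0 compartments. They were not run within compartments, nor was a second annotation, which the table does not hold.

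With 1 animal left out the counts ran from 7 to 13, 0 to 1 and 2 to 4 for types, from 3 to 5, 0 to 1 and 0 to 2 for compartments, and from 2 to 7, 0 to 2 and 0 to 6 within compartments. The calls on cells, UMIs, genes and mitochondrial percent per animal stayed at 0 (0 to 0), and those on UMIs or genes within types ran from 0 to 1. Phases and scores gave 3 calls, and 13 without lean rat 2, 8 of them for the G2M score in obese against lean rats. The immune share differed by 19.1 to 23.0, by -18.5 to -15.0 and by 2.46 to 6.39 points, and the covariance ran from -1.04 to -0.59. Without the 2 shallowest libraries the immune share of obese against lean rats differed by 19.1 points, with an exact p that can no longer pass because 3 lean animals are left.

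The replicate number as a block gave 12, 3 and 5 types, 5, 2 and 3 compartments, and 4, 0 and 0 types within compartments. The numbers were not shown to pair the animals, and the calls that this block made or ended are given beside the results. Depth sets a limit for lean rat 2, where 3 counts of 4232 cells stand for 0.0709%, and for Endo, with 38 cells in all.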

Other observations

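The tests of how other groupings of the animals behave were planned. The values of the log2 ratio of myeloid to distal cells and of TAL, PCT and other types under 5% mitochondrial UMIs were looked at after the main results were seen.

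Other low-mitochondrial cells were looked for beside the DCT cells. The percent of cells under 5% mitochondrial UMIs was 72.8% ± 16.5 in lean and 49.6% ± 14.6 in obese rats for PCT/PST, 67.4% ± 12.8 and 48.0% ± 11.1 for monocytes, and 65.9% ± 17.7 and 41.1% ± 12.6 for T cells. For Mono/Macro cells it was 65.4% ± 19.2 and 54.0% ± 15.1, for urothelial cells 63.8% ± 34.7 and 20.3% ± 13.3, and for IC-A/B cells 63.3% ± 10.0 and 47.3% ± 17.3. For glomerular endothelial cells it was 62.4% ± 15.1 and 44.0% ± 13.6, and for B cells 61.4% ± 26.0 and 23.2% ± 14.3. It was higher in obese than in lean rats for IC-B cells (4.51% ± 6.74 in lean and 9.66% ± 15.7 in obese rats). The same held for the few Endo cells (50% in lean and 59.5% ± 11.2 in obese rats). In lean rats 52.1% ± 30.4 of TAL cells had under 5% mitochondrial UMIs, against 8.84% ± 6.40 in obese rats, and the medians were 8.33% ± 8.69 and 28.8% ± 8.60 (exact two-sided permutation p = 0.0286, not adjusted, 1 of several types looked at). For PCT cells the medians were 10.9% ± 6.56 and 21.5% ± 2.62. DCT/CNT cells, which lie next to the DCT along the nephron, had medians of 21.6% ± 7.78 and 21.9% ± 2.55. Among cells under 5% mitochondrial UMIs, DCT made up 9.34% ± 2.94 of the cells in lean rats, 0.705% ± 0.50 in obese rats and 1.01% ± 0.284 in treated rats.

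Outside the proximal tubule, immune cells made up 25.2% ± 9.97 of the cells in lean rats, 62.5% ± 10.6 in obese rats and 43.2% ± 4.31 in treated rats. The treated rats so lay 18.0 points above the lean rats on this scale and 4.37 points above them among all cells. The log2 ratio of myeloid to distal cells was -0.59 ± 1.01 in lean, 2.69 ± 0.67 in obese and 0.97 ± 0.34 in treated rats.

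Other splits of the same animals were fitted to see how often they give as many calls, with 35 splits for each comparison and only the 2 groups in the fit. For obese against lean rats the real split gave 11 cell types, 5 compartments and 5 types within compartments. The highest of the other splits gave 2, 1 and 0. Only 1 of the 35 splits, the real one, gave as many, which is the lowest count that 35 splits allow. This argues against chance but cannot exclude it, and the exact permutation test of logit shares called 0 in each family. For treated against untreated obese rats chance cannot be excluded, with 1 cell type (2 splits gave as many, the highest other 1) and 1 compartment (4 splits, the highest other 1). For treated obese against lean rats it cannot be excluded either, with 3 cell types (2 splits, the highest other 4) and 2 types within compartments (2 splits, the highest other 4). Where the real split gave 0 calls, all 35 splits give as many by construction and nothing is shown: this holds for types within compartments in treated against untreated obese rats (the highest other 3) and for compartments in treated obese against lean rats (the highest other 1).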
